A study of Mus musculus with 19 samples.

How the data were processed

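The values used here were the authors' deposited raw count of reads per protein-coding gene, 1 column for each of 19 mouse liver libraries, with 21950 genes. Per the labels, RNA was taken from frozen liver with DNase treatment and sequenced as TruSeq stranded total RNA libraries. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned with HISAT2 to the mm10 mouse genome and counted with featureCounts. The versions of these tools, the gene annotation release and the strand setting of the counting were not given in the sources used here. Reads were not reprocessed. The counts were whole numbers whose sums differed between libraries, and no library was left out of the fit.

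Columns were matched to libraries by the label number that heads each column. Genes kept their deposited identifier, and 44 table lines share a symbol with another line. Another 27 symbols had been turned into dates and were replaced through their identifier. Coordinates came from the GENCODE M21 annotation of the mm10 build, in which 21886 of the 21950 identifiers were found. Because that annotation may differ from the one used for counting, coordinates serve only to identify genes.

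Counts were analysed with the edgeR quasi-likelihood method (edgeR 4.0.16, limma 3.58.1, R 4.3.3). The 4 groups of sex and diet were fitted as 4 means, with scaling by the trimmed mean of M values (TMM). Genes were kept by the edgeR expression filter (minimum count 10, minimum total 15), which left 13391 genes holding 99.977% of all counts. The biological coefficient of variation was 0.179, with 15 residual degrees of freedom and 5.11 prior degrees of freedom. CPM are counts scaled to library total times TMM factor (total alone for Ddx3y), with a prior count of 2 for log2 CPM. Standard errors (SE) were obtained from the fitted log2 fold change and its test statistic. Standard deviations (SD) are between libraries of a group.

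Before the data were examined, 5 comparisons were fixed: malnourished minus control in males, the same in females, the difference of those (female response minus male response, called the interaction), and female minus male within each diet. Adjusted p-values are Benjamini-Hochberg values over all tested genes of a comparison, with calls made at 0.05. The words rose and fell are used only for called genes. Genes singled out by rule were the 8 largest called changes in each direction (5 between the sexes) with a mean of at least 2 CPM over all 19 libraries. Except in the interaction, they also had to show no overlap in CPM between the compared groups. Up to 3 members of each gene list with the smallest adjusted p were added. Members of the fixed coagulation, nuclear receptor and related lists could be named whether or not they were called. Some genes that these rules pick, and a few other list members, are not reported here. For genes with hardly any counts in a group, a ratio of group counts with its counting interval replaces the fold change.

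A total of 35 gene lists with 469 members, 452 of them tested, were written from general knowledge before the data were examined. They cover procoagulant factors, anticoagulants, fibrinolysis and the vitamin K cycle. They also cover PPARα targets, FXR targets, bile acid synthesis, lipogenesis, cholesterol synthesis, the amino acid response, urea cycle and amino acid catabolism, and gluconeogenesis. Others are male-biased liver genes, female-biased liver genes, the growth hormone and IGF1 axis, acute phase, complement, xenobiotic metabolism, NRF2 targets, cell cycle, the unfolded protein response, oxidative phosphorylation and mitochondrially encoded genes. Markers of pericentral and periportal hepatocytes, Kupffer cells, stellate cells, sinusoidal endothelium, cholangiocytes, T and NK cells, B cells, neutrophils, red cells, adipocytes and exocrine pancreas complete the set. The lists were not checked against a database, and 12 members stand in more than 1 list. No adipocyte marker passed the expression filter and 1 exocrine pancreas marker did, so 33 lists could be tested.

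Each list was tested against all other genes with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with the correlation estimated from these libraries, and the rotation test fry, were run beside it. A list median is the middle log2 fold change of its tested members. Member counts are given by the adjustment over all genes and by an adjustment over the list alone.

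Alternatives comprised scaling by library size alone, DESeq2 (1.42.0), limma-voom with quality weights, the edgeR relative log expression scaling, TMM without the 50 most counted genes, label number series as a covariate, a 2-fold threshold, a higher expression floor, fits of 2 groups only, removal of each library in turn, removal of the 3 libraries whose label numbers begin with 62, and replicate numbers as a block. Removal of male controls 1 and 2, and of male controls 1, 2 and 3, was added after values had been seen. For each comparison 75 splits of its libraries, the real one among them and the others drawn at random, were fitted too. For the self-test, counts were drawn from the real means, library sizes and dispersions, with 200 genes changed by known factors. It recovered 76.1% of genes changed 2-fold in the male comparison (13300 genes, 4 false calls), 77.6% in the female (13309 genes, 11 false), and 53.7% in the interaction (13308 genes, 7 false). At 1.5-fold recovery was 28.4%, 56.7% and 14.9%. With 13305 genes, 2 of 2 lists moved on purpose were called and 1 unmoved list was called. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.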

Results

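Liver RNA from 19 C57BL/6J mice was counted for 21950 protein-coding genes. The mice formed 4 groups: 4 control males, 5 malnourished males, 5 control females and 5 malnourished females. Control food held 15% fat, 20% protein and 65% carbohydrate, and the malnourishing food of equal energy held 5%, 7% and 88%. Diets were assigned to nursing mothers at pup day 8, the young stayed on the mother's diet from day 21, and livers were collected at 8 weeks. Library totals ran from 21377385 to 33501907 counts. In megacounts, group means in the order above were 28.05 ± 3.75 (SD), 30 ± 2.52, 29.26 ± 4.67 and 28.8 ± 2.42, so depth was similar between groups. Litters and cages were not given, so p-values measure the spread between individual mice.

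The study's title names coagulopathy, sexual dimorphism and nutrient-sensing nuclear receptors. The comparisons below ask which genes the poor diet changed in each sex, where the responses differed, and how the sexes differed within each diet. The Y-linked gene Ddx3y stood at 20.7 to 35.3 CPM in all 9 male libraries and at no more than 0.0691 CPM (2 counts) in the 10 female libraries. The first principal component held 43.8% of the variance and the second 14.8%. On the first, male controls lay between -64.89 and -47.48, malnourished males between -32.06 and 10.66, control females between 6.51 and 17.13 and malnourished females between 39.19 and 46.08. Between replicates of the same group the smallest chi-square per degree of freedom was 15.7, so no library was a copy of a group mate.

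**Figure D1:**
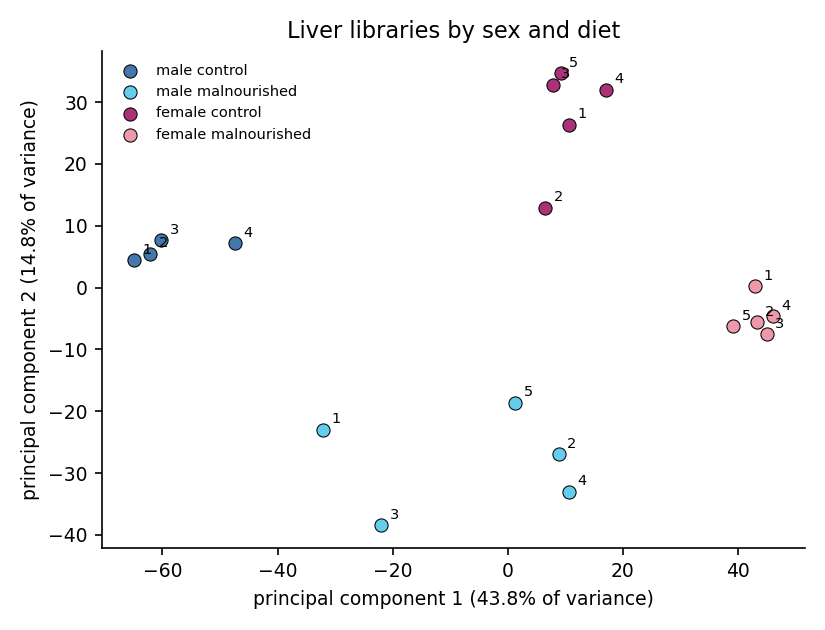
Each dot is 1 liver library, coloured by sex and diet and numbered by replicate, with principal component 1 (43.8% of variance) across and principal component 2 (14.8%) up. Malnourished males spread from -32.06 to 10.66 along component 1 and reach the range of control females (6.51 to 17.13).

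The male diet comparison (5 malnourished against 4 control) asks what the poor diet did to the male liver. Of 33 gene lists 19 passed camera, and 0 with an estimated correlation (lowest adjusted p = 0.137). Of 13391 tested genes, 952 rose and 1045 fell, together 14.9%. Changes of at least 2-fold were called for 383 and 325. Scaling by library size alone moved the median of all genes by 0.089 and the share of called genes that were higher from 47.7% to 64.8%.

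Among the largest rises in males was Cyp2b9, a cytochrome P450 (mm10 chromosome 7, 26173411 to 26210661). It rose from 0.426 ± 0.413 (SD, n = 4) to 201 ± 178 CPM (n = 5), a log2 change of 8.80 ± 0.92 (SE, adjusted p = 2.62e-06). Acot3, an acyl-CoA thioesterase, rose by 7.76 ± 1.01 (adjusted p = 2.6e-05). Hao2, a peroxisomal oxidase, rose by 7.16 ± 0.74 (2.43e-06), and Cyp2a4, a steroid hydroxylase, by 7.06 ± 0.82 (8.29e-06). The fatty acid hydroxylase Cyp4a14 went from 18.5 ± 23.6 to 1660 ± 594 CPM, or 6.48 ± 0.72 (5.33e-06). The transporter Slc22a26 rose by 6.18 ± 0.89 (7.32e-05) and Cyp2a22 by 6.13 ± 0.70 (6.82e-06). Without male control 4, Cyp2b9 gave 9.85, Acot3 9.3, Hao2 7.98 and Cyp4a14 7.95. Reads of the Cyp2a, Cyp2b, Cyp4a and Acot families can be shared between near-identical copies, so which copy changed is uncertain.

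The largest falls in males included Nnmt, a nicotinamide methyltransferase (chromosome 9, 48591877 to 48605153). It dropped from 91.7 ± 42.8 to 0.934 ± 0.493 CPM, a log2 change of -6.6 ± 0.35 (adjusted p = 1.94e-10, 97-fold). The ferritin receptor Scara5 (-6.42 ± 0.53, 1.47e-07), the calcium-binding Cib3 (-5.78 ± 0.39, 1.08e-08) and the predicted gene Gm3839 (-4.89 ± 0.24, 1.24e-10) fell too. The serum amyloids Saa2 and Saa1 fell by 6.09 ± 0.76 (1.83e-05) and 5.73 ± 0.65 (6.77e-06), Saa1 from 981 ± 952 to 18.4 ± 8.27 CPM. Male controls 1 to 4 held 2250, 1120, 489 and 64.7 CPM of Saa1, so the control mean rests on 3 of 4 mice. Orm3, an orosomucoid, fell by 4.66 ± 0.85 (0.000783) and the pheromone carrier Mup7 by 4.45 ± 0.93 (0.00239). Without male control 1, Saa2, Saa1 and Orm3 gave -4.92, -4.89 and -2.88. Scara5 gave -7.61 and Mup7 -6.27 without malnourished male 1, and Cib3 -6.73 without malnourished male 3. The male-biased Moxd1 had a control to malnourished count ratio of 956 (counting interval 171 to 37800).

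Most listed targets of PPARα, the nuclear receptor that switches on fatty acid oxidation, rose in males. Of 33 tested members 26 rose, 0 fell and the rest did not pass (28 and 0 adjusted over the list alone), with a median log2 change of 0.72. The list as a whole moved up (camera adjusted p = 1.38e-22, and adjusted p = 0.137 with an estimated correlation). Beside Cyp4a14 and Acot3, Cyp4a10 rose by 3.99 ± 0.49 (1.38e-05), Pdk4, which spares glucose, by 3.34 ± 0.47 (5.63e-05), Acot4 by 2.75 ± 0.27 (1.63e-06), and the fatty acid importer Cd36 by 2.54 ± 0.40 (0.000209). Without male control 4, Cyp4a10 gave 4.98 and Cd36 3.18. The hepatokine Fgf21 (chromosome 7, 45613886 to 45615490) rose by 3.87 ± 0.62 (0.00022, 14.6-fold). Not called were Cpt1a (-0.16, adjusted p = 0.537) and the receptor gene Ppara itself (-0.22 ± 0.32, 0.699).

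Among 10 targets of the bile acid receptor FXR, 5 rose and 0 fell, with the same counts over the list alone and a median of 0.66 (camera adjusted p = 0.00484, and adjusted p = 0.195 with an estimated correlation). They were Pltp (1.5, adjusted p = 0.0055), Fetub (0.42, 0.0103), Osgin1 (1.18, 0.0179), Akr1b7 (2.60, 0.0202) and Abcb4 (0.40, 0.0318). Osgin1 lost its call without male controls 2 (1.05, 0.0691) or 3 (1.05, 0.0655) or malnourished male 2 (0.90, 0.0575). Akr1b7 (3.23 without male control 1) lost it without male controls 2, 3 or 4 or malnourished male 2 (1.93; 0.0502 to 0.0692), and Abcb4 without male controls 1, 2 or 3 or malnourished males 2 or 3 (0.0503 to 0.0872). Nr1h4, which encodes FXR, gave 0.24 ± 0.16 (0.327) and its target Nr0b2 0.90 ± 0.39 (0.132), which was called without male control 1 (1.41, 0.0271) or malnourished male 4 (1.17, 0.0247). Of 14 bile acid synthesis genes 1 rose and 1 fell (2 and 4 over the list alone, median -0.14, camera adjusted p = 0.213). The oxysterol hydroxylase Cyp7b1 fell by 3.53 (1.9e-05), from 324 ± 59.3 to 28.2 ± 28.5 CPM (-4.34 without malnourished male 1), and Cyp39a1 rose by 1.27 (3.81e-05). Cyp7a1, the first enzyme of the main route, gave -1.04 ± 0.67 (0.327).

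Of 21 amino acid response genes 12 rose and 1 fell in males (14 and 3 over the list alone), median 0.66, camera adjusted p = 3.32e-05, and adjusted p = 0.18 with an estimated correlation. Asns, asparagine synthetase (chromosome 6, 7675169 to 7693254), rose by 3.56 ± 0.44 (1.76e-05), and the serine synthesis genes Phgdh and Psat1 rose by 3.51 ± 0.68 (0.00136; 2.90 without malnourished male 4) and 3.28 ± 0.52 (0.000201). The member that fell was Cth (-0.71, 0.00199). Of 27 genes of the urea cycle and amino acid catabolism 20 fell and 0 rose (25 and 0 over the list alone), median -0.74, camera adjusted p = 4.96e-16, and adjusted p = 0.137 with an estimated correlation. Tat fell by 2.02 ± 0.37 (0.000848), Ass1 by 1.34 ± 0.23 (0.000504), Gls2 by 1.32 ± 0.20 (0.000162) and the first urea cycle enzyme Cps1 by 1.31 ± 0.26 (0.00179).

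In the 18-gene lipogenesis list 3 rose and 2 fell in males (the same over the list alone), median -0.08, camera adjusted p = 0.821. Risers were Elovl5 (1.11, 0.000311), Me1 (1.25, 0.00212) and Pnpla3 (1.83, 0.0295), the last not called without male controls 2, 3 or 4 or malnourished male 4 (0.0515 to 0.11). Of those that fell, Thrsp changed by -1.22 (0.0346), but it was not called without male controls 1, 2 or 3 or malnourished males 1, 2, 4 or 5 (0.0519 to 0.123). Of 24 cholesterol synthesis genes 0 rose and 2 fell (same over the list alone), Dhcr7 (-0.87, 0.00192) and Mvk (-0.74, 0.00606). The median was -0.41 (camera adjusted p = 0.000127, and adjusted p = 0.405 with an estimated correlation). Of 8 gluconeogenesis genes 0 rose and 2 fell (3 over the list alone), median -0.24, camera adjusted p = 0.345. They were Foxo1 (-0.70, 0.0139), not called without male control 1 (-0.48, 0.0946), and Slc37a4 (-0.48, 0.0263), not called without male controls 1 or 3 or malnourished males 2, 3 or 4 (0.052 to 0.155).

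Many listed sex-typical genes shifted in males. Of 25 female-biased liver genes 19 rose and 0 fell (24 and 0 over the list alone), median 2.67, camera adjusted p = 8.26e-13, and adjusted p = 0.137 with an estimated correlation. The shift was uneven, with Cyp2b9 at 16.5 and 30.2 CPM in malnourished males 1 and 3 and 256 to 438 CPM in the others. Beyond the enzymes above, the female-biased transcription factor Cux2 rose by 3.76 ± 0.90 (0.00678; 2.99 without malnourished male 4) and the prolactin receptor Prlr by 1.86 ± 0.23 (1.76e-05). Of 23 male-biased genes 16 fell and 0 rose (18 and 0 over the list alone), median -1.93, camera adjusted p = 6.85e-19, and adjusted p = 0.137 with an estimated correlation. Susd4, a complement inhibitor, fell by 4.35 ± 0.50 (6.74e-06) and the complement component C6 by 3.70 ± 0.42 (6.82e-06), and without malnourished male 1 by 5.41 and 4.37. In the growth hormone and IGF1 axis of 12 genes 1 rose, Igfbp2 (0.67, 0.0391), and 1 fell, Igfbp4 (-0.46, 0.0116), with 2 and 1 over the list alone, median -0.07 and camera adjusted p = 0.796. Igfbp2 was not called without male controls 1, 2, 3 or 4 or malnourished males 2, 3 or 4 (0.0532 to 0.119). Igf1 gave -0.14 ± 0.17 (0.642), and Bcl6, a male-typical repressor, 0.69 ± 0.41 (0.278).

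Few clotting genes changed in males. Of 15 procoagulant factors 1 fell and 0 rose, the same over the list alone, with a median of -0.17 (camera adjusted p = 0.056, passing in 4 of 19 removals of 1 library, lowest 0.0215). It was F11, clotting factor XI (chromosome 8, 45241174 to 45262031), which fell from 184 ± 30.8 to 90.2 ± 35.5 CPM (-1.03 ± 0.27, adjusted p = 0.0125, 2.04-fold). Fga, Fgb and Fgg, the fibrinogen chains, gave -0.41 ± 0.15 (0.073), -0.36 ± 0.13 (0.0663) and -0.27 ± 0.15 (0.223). Fga was called without male control 4 (-0.53, 0.0116) or malnourished male 2 (-0.52, 0.0274), and Fgb without male control 4 (-0.44, 0.0162). Also not called were F2 (-0.06, 0.72), F5 (-0.23, 0.415), F7 (-0.21, 0.262), F8 (0.27, 0.61), F9 (-0.16, 0.324), F10 (-0.11, 0.501), F12 (-0.17, 0.217) and F13b (-0.26, 0.269).

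Some natural anticoagulants fell in males. Of 11 members 4 fell and 0 rose (5 fell and 1 rose over the list alone), median -0.29, camera adjusted p = 0.0491, and adjusted p = 0.262 with an estimated correlation. That call was lost in 12 of 19 removals of 1 library (highest 0.0838), and without male controls 1, 2 and 3 (camera adjusted p = 0.366, median -0.11 and 0 called of 12 tested members). Serpina10, the inhibitor of factor X, fell by 0.81 (0.000783), Serpind1, heparin cofactor II, by 0.55 (0.00697), Pros1, protein S, by 0.29 (0.0281) and Proz, protein Z, by 0.33 (0.0289). Pros1 lost its call without male controls 1 (-0.22, 0.134) or 3 (-0.23, 0.134), malnourished male 4 (-0.23, 0.0968) or female control 1 (-0.26, 0.0506), and Proz without male controls 1, 2 or 3 or malnourished males 3, 4 or 5 (0.0631 to 0.115). Serpinc1, antithrombin, gave -0.04 (0.808) and Proc, protein C, -0.05 (0.792).

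Of 7 fibrinolysis genes 3 fell and 0 rose in males (5 over the list alone), median -0.39, camera adjusted p = 0.0143, and adjusted p = 0.195 with an estimated correlation. Cpb2, a clot stabiliser, fell by 0.51 (0.0115), not called without male control 1 (-0.43, 0.0579). Plaur, the urokinase receptor, fell by 1.32 (0.0242), not called without male controls 1, 2 or 3 or malnourished males 3, 4 or 5 (0.0524 to 0.103). Plg, plasminogen, gave -0.31 ± 0.12 (0.0783) and was called without malnourished male 1 (-0.37, 0.0286). In the vitamin K cycle, which activates several clotting factors, 1 of 6 genes rose and 0 fell, with 1 and 0 over the list alone, median 0.10 and camera adjusted p = 0.284. It was Nqo1 (1.64, 7.44e-05).

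Of 17 acute phase genes, made by the inflamed liver, 10 fell and 0 rose in males, the same over the list alone, median -1.02, camera adjusted p = 3.6e-06, and adjusted p = 0.262 with an estimated correlation. Lcn2 fell by 4.54 ± 0.77 (0.000373), Orm1 by 2.88 ± 0.31 (3.35e-06) and the metalloreductase Steap4 by 2.55 ± 0.35 (4.85e-05), and without male control 1 Lcn2 by 2.74 and Steap4 by 1.97. Without male controls 1, 2 and 3, which held the most Saa1, the acute phase median was 0.07 (camera adjusted p = 0.709). Of 19 complement genes 9 fell and 1 rose (11 and 1 over the list alone), median -0.41, camera adjusted p = 4.07e-06, and adjusted p = 0.195 with an estimated correlation. C9 fell by 2.40 ± 0.39 (0.000234) and Hc, component 5, by 1.01 ± 0.14 (4.66e-05), while Mbl2 rose by 0.62 (0.00117). Without male controls 1, 2 and 3 the complement median was -0.22 with 1 gene lower (camera adjusted p = 0.0286), and without 1 and 2 it was -0.36 with 3 lower.

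Of 16 xenobiotic metabolism genes 8 rose in males and 1, Alas1 of haem synthesis (-1.43, 0.0453), fell (11 and 1 over the list alone), median 0.96, camera adjusted p = 1.33e-07, and adjusted p = 0.137 with an estimated correlation. The bile and drug exporter Abcc3 rose by 2.37 ± 0.21 (3.81e-07), Nr1i3, the drug sensor CAR, by 1.64 ± 0.17 (1.97e-06) and Cyp3a11 by 1.77 ± 0.20 (6.77e-06). Alas1 lost its call in 12 of 19 removals of 1 library, most without male control 2 (-0.91, 0.248) or malnourished male 2 (-1.31, 0.0947). Of 11 NRF2 targets, which counter oxidants, 3 rose and 0 fell (4 and 0 over the list alone), median 0.37, camera adjusted p = 0.045, lost in 9 of 19 removals of 1 library (highest 0.112), and adjusted p = 0.396 with an estimated correlation. These were Nqo1, Gclc (0.91, 0.000267) and Gstm1 (1.39, 0.000397). In the 18-gene cell cycle list 3 rose and 0 fell (7 and 0 over the list alone), median 0.68, camera adjusted p = 0.00142, and adjusted p = 0.396 with an estimated correlation. Aurkb rose by 1.39 (0.00113), Cdc20 by 1.34 (0.0387), not called without male controls 2 or 4 or malnourished males 2 or 5 (0.0831 to 0.11), and Top2a by 1.03 (0.0424), not called without any single male control, malnourished males 2, 4 or 5 or malnourished females 3 or 4 (0.0504 to 0.121).

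Stress and energy lists did not pass in males. Of 14 unfolded protein response genes 0 were called over all genes or over the list alone (median -0.15, camera adjusted p = 0.413, 2 members at unadjusted p below 0.05 in edgeR). None of 23 oxidative phosphorylation genes (median -0.05, 0.157) and none of 13 mitochondrially encoded genes (-0.03, 0.344) was called, with 0 over each list alone too. Among 9 pericentral markers Axin2 rose (1.19, 0.00539), and Slc1a2 (-0.75, 0.00322), Oat (-1.09, 0.0141) and Cyp1a2 (-0.81, 0.0237) fell (median -0.08, camera adjusted p = 0.282). Cyp1a2 was not called without male controls 1, 2 or 3 or malnourished males 4 or 5 (0.051 to 0.0859). Among 8 periportal markers 0 rose and 4 fell (the same over the list alone), Sds (-1.96), Gls2 (-1.32), Cyp2f2 (-0.92) and Hal (-0.66), with a median of -0.62 (camera adjusted p = 0.0129, and adjusted p = 0.262 with an estimated correlation). Hal was not called without male controls 1 (-0.60, 0.0612) or 3 (-0.59, 0.0631).

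Some blood and other cell markers shifted in males. All 4 B cell markers rose (4 over the list alone), median 1.39, camera adjusted p = 0.000821, and adjusted p = 0.137 with an estimated correlation. Cd79a rose by 1.51, Ms4a1 by 1.5 and Cd79b by 1.14. Ms4a1 was not called without male control 2 (1.26, 0.0575), and gave 2.20 without male control 4. Of 5 red cell markers 4 rose, the haemoglobins Hbb-bt (1.5), Hba-a2 (1.48), Hbb-bs (1.31) and Hba-a1 (1.27), and Alas2 fell (-1.30, 0.00287), with a median of 1.31 (camera adjusted p = 0.00423, and adjusted p = 0.249 with an estimated correlation). The 3 neutrophil markers fell, S100a8 by 2.22, S100a9 by 2.52 and Retnlg by 2.74, median -2.52, camera adjusted p = 0.167. Without male control 1 none was called (-1.27 and 0.118, -1.59 and 0.0593, -1.38 and 0.272). Kupffer cell markers (10 genes, 1 rose, Timd4 by 0.40, 0.0331) had a median of 0.20 (camera adjusted p = 0.045, lost in 7 of 19 removals, highest 0.168, and adjusted p = 0.542 with an estimated correlation). Timd4 was not called without male controls 1, 2 or 4 or malnourished males 2 or 5 (0.0549 to 0.0704). Sinusoidal endothelial markers (7 genes, 0 called, median 0.33) passed camera (0.00577, and adjusted p = 0.396 with an estimated correlation) but not without male controls 1 (0.0689) or 2 (0.0575). Stellate cell (8 genes, median 0.08, camera adjusted p = 0.672), cholangiocyte (5, -0.34, 0.224) and T and NK cell markers (7, 0.23, 0.157) had 0 calls.

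**Figure D2:**
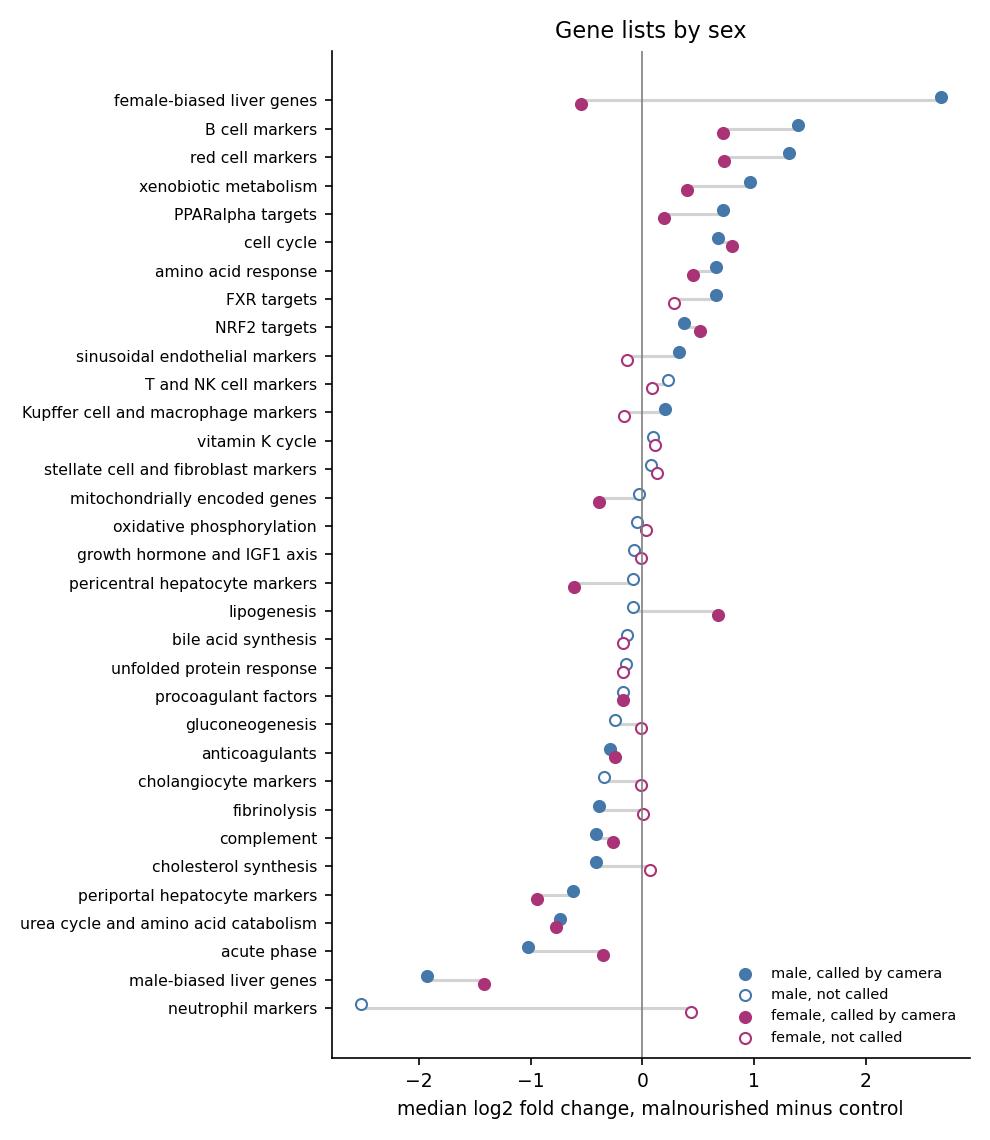
Dots give the median log2 fold change (malnourished minus control, across) of each tested gene list, blue for males and purple for females, filled where camera called the list. Female-biased liver genes lie at 2.67 in males and -0.55 in females, and urea cycle genes at -0.74 and -0.77.

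The female diet comparison (5 against 5) asks the same question of the female liver. Of 33 gene lists 18 passed camera, and 0 with an estimated correlation (lowest adjusted p = 0.145). Of 13391 genes 691 rose and 668 fell, together 10.1%, with 242 and 200 by at least 2-fold. Without female control 3, 433 fell. Scaling by library size alone moved the median of all genes by 0.10 and the share of called genes that were higher from 50.8% to 73.2%.

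The largest rises in females were the sulfotransferase Sult2a3 (5.74 ± 0.55 (SE), adjusted p = 1.46e-06) and Asns (4.95 ± 0.45, 6.79e-07), which went from 0.595 ± 0.124 (SD, n = 5) to 18.3 ± 9.56 CPM (n = 5). The sorting receptor Sorcs2 rose by 4.18 ± 0.48 (1.05e-05), Phgdh by 4.08 ± 0.59 (0.000108), Sult2a5 by 3.80 ± 0.61 (0.000348) and Psat1 by 3.56 ± 0.48 (5.65e-05). The lysosomal membrane gene Cd63 rose by 3.02 ± 0.22 (3.83e-08), from 5.81 ± 0.816 to 47.2 ± 11.2 CPM, and the receptor Adgrg2 by 3.01 ± 0.41 (6.9e-05). Falls were led by the pheromone carrier Mup10 (-7.86 ± 0.83, 3.79e-06), which went from 544 ± 276 to 2.29 ± 3.11 CPM. Mup13 (-7.09 ± 0.73, 3.08e-06), Mup1 (-6.79 ± 1.25, 0.00127) and Mup11 (-6.00 ± 1.16, 0.00197) fell with it. The female-biased sulfotransferase Sult3a1 fell by 7.15 ± 0.66 (7e-07), the male-biased organic anion transporter Slco1a1 by 6.6 ± 0.59 (4.71e-07, 145 ± 62.1 to 1.48 ± 1.16 CPM) and Nnmt by 6.41 ± 0.34 (4.42e-10). Without female control 4, Sult2a3 gave 6.90 and Sult2a5 4.52, and without malnourished female 5 Mup10 gave -9.23 and Sult3a1 -9.02. Gm21320, annotated as Mup22, had a control to malnourished count ratio of 85.8 (counting interval 29 to 419). Reads of Mup and Sult2a genes can likewise be shared, so which copy changed is uncertain.

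Of 21 amino acid response genes 9 rose in females and 1, Cth (-0.97, 0.000102), fell (11 and 1 over the list alone), median 0.45, camera adjusted p = 8.99e-06, and adjusted p = 0.145 with an estimated correlation. Of 27 urea cycle and amino acid catabolism genes 21 fell and 0 rose (24 and 0 over the list alone), median -0.77, camera adjusted p = 2.27e-22, and adjusted p = 0.145 with an estimated correlation. The ornithine enzyme Oat fell by 2.07 ± 0.29 (6.9e-05), Tat by 1.88 ± 0.36 (0.00174), Agxt by 1.57 ± 0.19 (2.25e-05), Cps1 by 1.4 ± 0.25 (0.00106) and Ass1 by 1.26 ± 0.22 (0.000935). Of 8 gluconeogenesis genes 1 rose and 1 fell, the latter Pck1 (-1.66, 0.00996), with a median of -0.01 (camera adjusted p = 0.926).

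Of 33 PPARα targets 3 rose and 0 fell in females (3 and 1 over the list alone), median 0.19, camera adjusted p = 0.0157, lost in 4 of 19 removals of 1 library (highest 0.105), and adjusted p = 0.66 with an estimated correlation. They were Fgf21 (3.18 ± 0.55, 0.000686; 3.83 without female control 2), Cd36 (1.63 ± 0.36, 0.00526) and Acaa1b (0.60 ± 0.19, 0.0488). Acaa1b lost its call in 13 of 19 removals, among them female control 3 (0.50, 0.145) and malnourished female 2 (0.53, 0.126). Cyp4a14 gave 0.33 ± 0.51 (0.758) and Ppara -0.41 ± 0.30 (0.438). Of 10 FXR targets 4 rose and 1 fell (median 0.28, camera adjusted p = 0.125): Akr1b7 (2.24), Slc51b (1.91, 0.00927), Pltp (1.2) and Osgin1 (1.01) against Sdc1 (-0.66, 0.0116). Osgin1 was not called without female controls 1, 3, 4 or 5 or malnourished females 2, 3, 4 or 5 (0.0722 to 0.113). Nr1h4 gave -0.08 (0.804) and Nr0b2 0.54 ± 0.37 (0.407). Of 14 bile acid synthesis genes 1 fell, Cyp27a1 (-0.63, 0.00351), and 0 rose (3 and 0 over the list alone), median -0.17, camera adjusted p = 0.244, with Cyp7a1 at 0.08 ± 0.62 (0.956).

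In the 18-gene lipogenesis list 6 rose and 0 fell in females (9 and 0 over the list alone), median 0.68, camera adjusted p = 1.04e-05, and adjusted p = 0.19 with an estimated correlation. Pnpla3 rose by 2.15 ± 0.50 (0.00842), Elovl6 by 1.42 ± 0.32 (0.00619), Me1 by 1.41 ± 0.24 (0.000599), Acaca, which makes malonyl-CoA, by 1.19 ± 0.27 (0.00599), Pklr by 1.10 ± 0.23 (0.0034) and Acly by 1.06 ± 0.28 (0.0176). Acly was not called without malnourished females 1 (0.91, 0.0541) or 2 (0.91, 0.0591). Of 24 cholesterol synthesis genes 1 fell, Ebp (-0.49, 0.00743), and 0 rose (median 0.07, camera adjusted p = 0.412).

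Some listed sex-typical genes of both kinds fell in females, though a wider set of 634 female-biased genes (last paragraph) did not (median -0.022). Of 25 female-biased genes 9 fell and 1 rose (13 and 1 over the list alone), median -0.55, camera adjusted p = 7.48e-06, and adjusted p = 0.228 with an estimated correlation. Cyp3a41a fell by 4.51 ± 0.50 (8.21e-06), A1bg by 2.94 ± 0.51 (0.000783) and Cyp3a44 by 1.57 ± 0.24 (0.000194). Without malnourished female 1, Cyp3a41a gave -5.21 and A1bg -3.56. The riser was the bile acid sulfotransferase Sult2a1 (2.54 ± 0.68, 0.0206), not called without female control 3 (2.33, 0.0625). Of 23 male-biased genes 11 fell and 1 rose (13 and 1 over the list alone), median -1.42, camera adjusted p = 1.19e-06, and adjusted p = 0.329 with an estimated correlation. The steroid enzyme Hsd3b5 fell by 4.83 ± 0.79 (0.000407), while Gstp1 rose by 0.89 (0.0274), not called without female controls 1, 3, 4 or 5 or malnourished females 2, 3 or 4 (0.0543 to 0.0688). In the growth hormone and IGF1 axis of 12 genes 4 fell and 0 rose (4 and 1 over the list alone), median -0.01, camera adjusted p = 0.111. Igf1 (chromosome 10, 87858265 to 87937042) fell from 541 ± 114 to 264 ± 38.5 CPM (-1.03 ± 0.16, 0.000277, 2.04-fold), its binding partner Igfals by 1.00 ± 0.18 (0.00106), the growth hormone receptor Ghr by 0.59 ± 0.14 (0.0095) and Igfbp4 by 0.46 (0.0111). Igfbp1 gave 1.58 ± 0.57 (0.0878) and was called without male control 1 (1.58, 0.0203).

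Clotting factors IX and XI fell in females. Of 15 procoagulant factors 2 fell and 0 rose (4 and 0 over the list alone), median -0.17, camera adjusted p = 0.00121, and adjusted p = 0.188 with an estimated correlation. F9 (chromosome X, 59999464 to 60030759) fell from 171 ± 17.9 to 113 ± 8.65 CPM (-0.60 ± 0.10, adjusted p = 0.000488, 1.52-fold) and F11 from 127 ± 24.8 to 59.2 ± 25.7 CPM (-1.10 ± 0.26, 0.00868, 2.14-fold). Not called were F2 (-0.04, 0.839), F7 (-0.19, 0.317), F8 (-0.38, 0.464), F10 (-0.07, 0.698), F12 (-0.05, 0.794), Fga (-0.05, 0.886), Fgb (-0.10, 0.671), Fgg (-0.17, 0.497), F5 (-0.41, 0.14) and F13b (-0.41, 0.0789). F5 was called without female control 2 (-0.52, 0.0433), and F13b without female control 2 (-0.47, 0.0469) or malnourished male 4 (-0.41, 0.0351). Of 11 anticoagulants 2 fell and 0 rose (the same over the list alone), Pros1 (-0.35, 0.00763) and Hrg, a heparin-binding plasma protein (-0.34, 0.037), with a median of -0.24 (camera adjusted p = 0.00709, and adjusted p = 0.171 with an estimated correlation). Hrg was not called without female controls 1, 3, 4 or 5 or any single malnourished female (0.0504 to 0.117). Of 7 fibrinolysis genes 1 fell, Cpb2 (-0.52, 0.0102), and 0 rose, the same over the list alone (median 0.01, camera adjusted p = 0.273), with Plg at -0.28 (0.122). In the vitamin K cycle 1 of 6 rose, Nqo1 (0.96, 0.00341), and 0 fell (median 0.11, camera adjusted p = 0.0702).

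**Figure D3:**
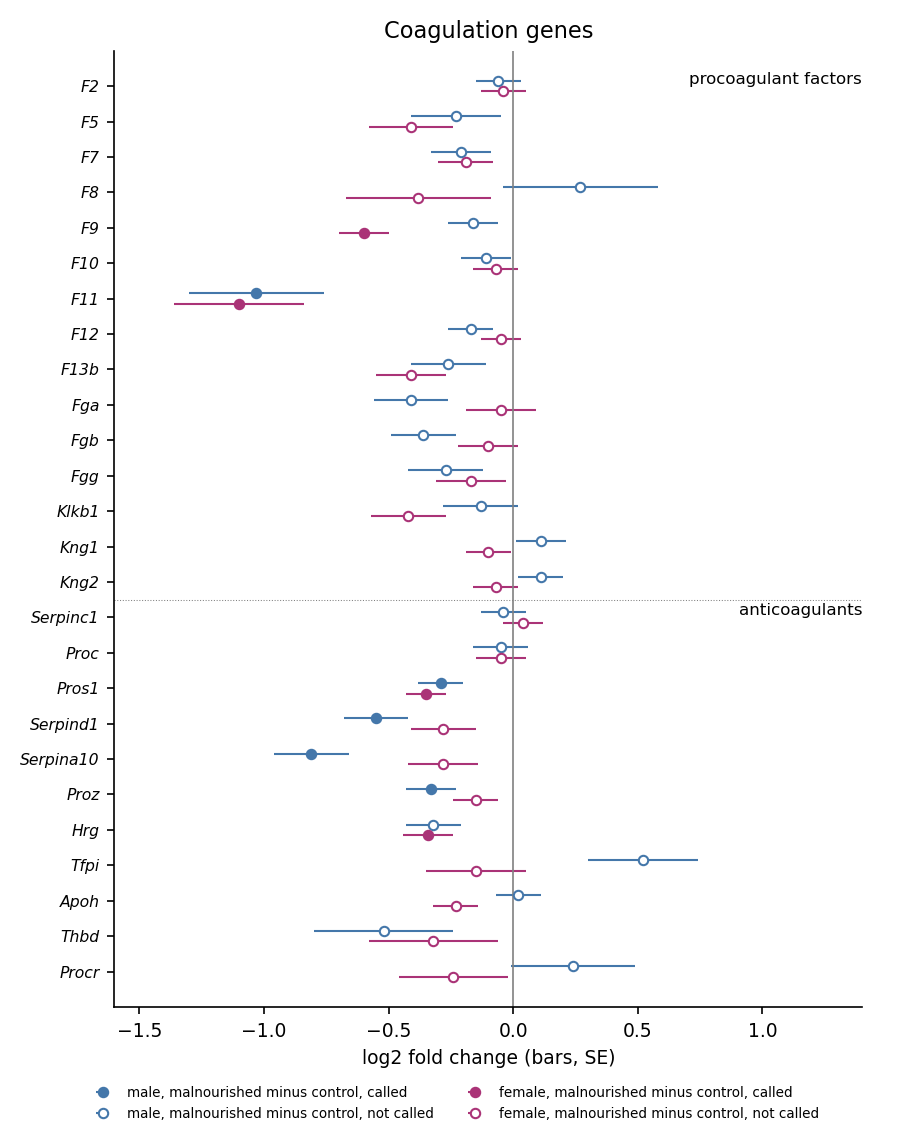
Log2 fold changes (across, bars SE) of 26 procoagulant and anticoagulant genes, blue for males and purple for females, filled where called. F11 fell in both sexes (-1.03 and -1.10), F9 was called in females (-0.60), and Serpina10 in males (-0.81, resting on the higher controls).

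Of 17 acute phase genes 3 fell and 0 rose in females (4 and 0 over the list alone), median -0.35, camera adjusted p = 0.000616, and adjusted p = 0.42 with an estimated correlation. The orosomucoids Orm3, Orm1 and Orm2 fell by 3.83 (0.00278; 3.18 without female control 4), 2.92 ± 0.30 (3.08e-06) and 2.07 (0.00162). Of 19 complement genes 4 fell and 0 rose (7 and 0 over the list alone), median -0.26, camera adjusted p = 3.64e-05, and adjusted p = 0.193 with an estimated correlation. C9 fell by 1.99 ± 0.37 (0.00144), C8b by 1.67 (0.00128), C8a by 1.34 ± 0.26 (0.00176) and Hc by 0.49 (0.0222), the last not called without female control 1 (-0.46, 0.0513) or malnourished females 2 (-0.48, 0.0503) or 4 (-0.42, 0.0689). Of 16 xenobiotic genes 7 rose and 0 fell (8 and 0 over the list alone), median 0.40, camera adjusted p = 3.64e-05, and adjusted p = 0.171 with an estimated correlation. Of 11 NRF2 targets 6 rose and 0 fell (8 and 0 over the list alone), median 0.52, camera adjusted p = 2.61e-05, and adjusted p = 0.145 with an estimated correlation. The glutathione transferases Gstm3 and Gstm1 rose by 2.30 ± 0.32 (7.99e-05) and 1.32 ± 0.22 (0.000488). In the 18-gene cell cycle list 8 rose and 0 fell (13 and 0 over the list alone), median 0.80, camera adjusted p = 1.23e-09, and adjusted p = 0.145 with an estimated correlation. The mitotic genes Plk1 and Ccnb2 rose by 1.46 ± 0.31 (0.0045) and 1.33 ± 0.27 (0.00283).

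Of 9 pericentral markers 4 fell and 0 rose in females (5 and 0 over the list alone), median -0.61, camera adjusted p = 0.000983, and adjusted p = 0.19 with an estimated correlation. They were Oat, Slc1a2 (-1.10, 8.3e-05), the alcohol oxidase Cyp2e1 (-0.73 ± 0.15, 0.00351) and Cyp1a2 (-0.82, 0.0234), which was not called without female control 3 (-0.69, 0.0829) or malnourished females 4 (-0.78, 0.0596) or 5 (-0.72, 0.0604). Of 8 periportal markers 6 fell and 0 rose (6 and 1 over the list alone), median -0.94, camera adjusted p = 2.61e-05, and adjusted p = 0.145 with an estimated correlation. Of 13 mitochondrially encoded genes 1 fell (2 over the list alone), mt-Co1 (-0.65, 0.0174), not called without female control 3 (-0.55, 0.0667), and the list median was -0.39 (camera adjusted p = 0.00709, and adjusted p = 0.551 with an estimated correlation). Of 4 B cell markers 2 rose (3 over the list alone), among them Cd79a (0.80, 0.0333), with a median of 0.72 (camera adjusted p = 0.00394, and adjusted p = 0.145 with an estimated correlation). Cd79a was not called without female controls 2, 3, 4 or 5 or malnourished females 1, 3 or 4 (0.0514 to 0.0885). Of 5 red cell markers 3 rose (5 over the list alone), Hba-a2 (1.13, 0.00525), Hbb-bt (0.88, 0.0171) and Hbb-bs (0.73), with a median of 0.73 (camera adjusted p = 0.000109, and adjusted p = 0.145 with an estimated correlation). Hbb-bs was not called without female controls 1, 4 or 5 (0.0509 to 0.0549), nor Hbb-bt without malnourished female 3 (0.78, 0.0541).

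The remaining female lists had 0 calls over all genes. They were the unfolded protein response (14 genes, median -0.17, camera adjusted p = 0.14, 2 members at unadjusted p below 0.05 in edgeR) and oxidative phosphorylation (23, 0.03, 0.552). Markers of Kupffer cells (10, -0.16, 0.244), stellate cells (8, 0.13, 0.927), endothelium (7, -0.14, 0.349), cholangiocytes (5, -0.01, 0.704), T and NK cells (7, 0.09, 0.7) and neutrophils (3, 0.44, 0.7) did not pass either.

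**Figure D4:**
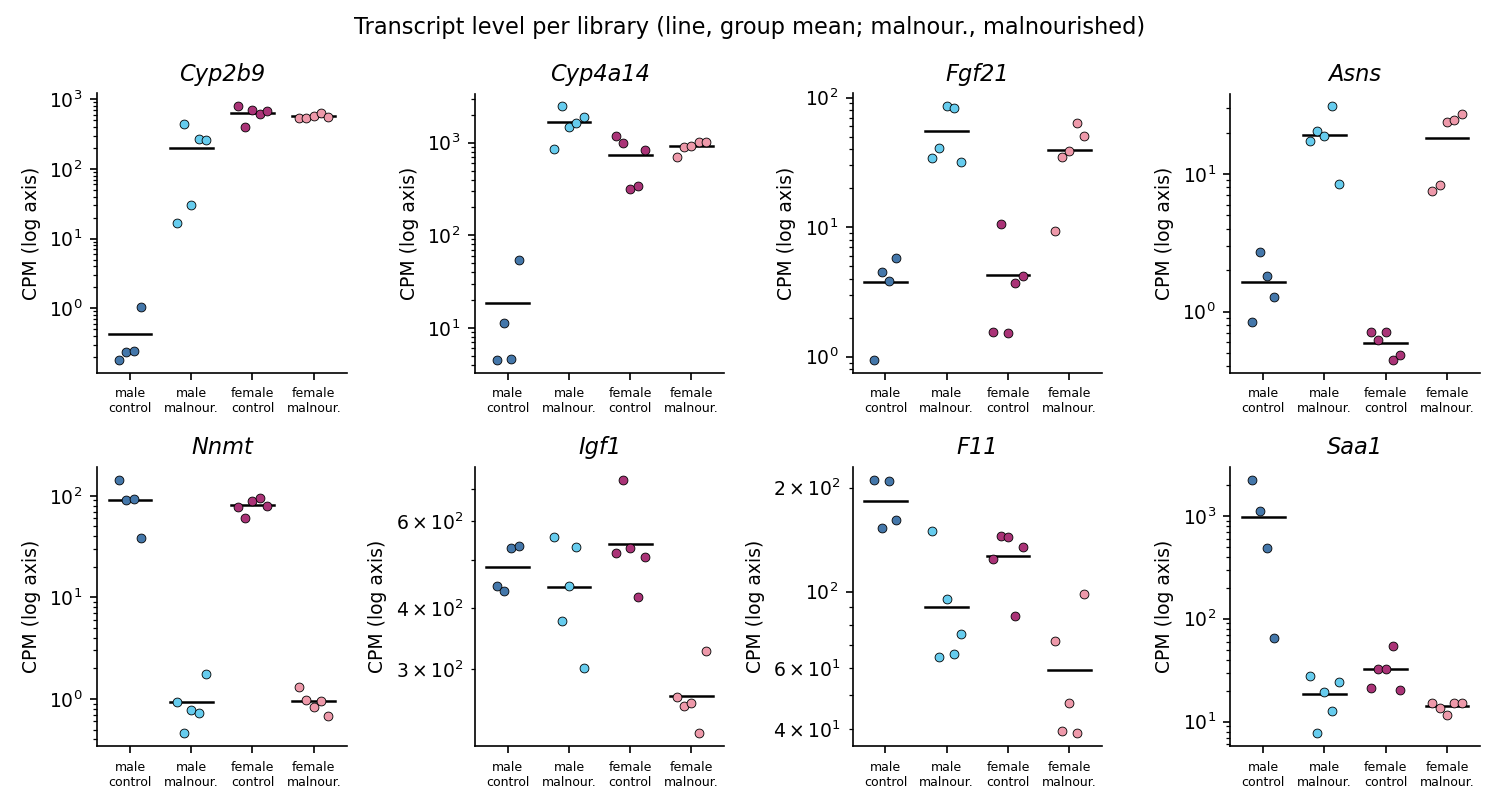
Each dot is the level of 1 gene in 1 library (CPM, log axis, up) by sex and diet (across), with a line at the group mean. Cyp2b9 rises from 0.426 to 201 CPM in males and stays near 639 and 571 CPM in females, while Nnmt falls to 0.934 and 0.954 CPM.

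The interaction (19 mice) asks where the sexes answered the diet differently. Differences were called for 280 of 13391 genes (2.09%), 113 higher and 167 lower in the female response, with 76 and 119 of at least 2-fold. Among removals of 1 library, counts moved most without male control 2 (63 and 95), male control 4 (229 and 379) or female control 5 (240 and 274), and fewer were higher without female control 1 (69), malnourished female 1 (73) or malnourished female 3 (72, and 110 lower). Larger moves came without the 3 libraries whose label numbers begin with 62 (380 and 470) and without male controls 1, 2 and 3 (4 and 4). Of the gene lists, female-biased genes and PPARα targets had the most calls. Among 25 female-biased genes 20 were lower and 0 higher (24 and 0 over the list alone), median -5.10, camera adjusted p = 2.84e-26, and adjusted p = 0.0607 with an estimated correlation. Among 33 PPARα targets 11 were lower and 0 higher (20 and 0 over the list alone), median -0.68, camera adjusted p = 1.58e-20, and adjusted p = 0.212 with an estimated correlation.

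Large negative differences included Sult3a1 (-11.18 ± 1.71 (SE), adjusted p = 0.00083), Cyp2b13 (-9.21 ± 1.74, 0.00525), Cyp2b9 (-8.97 ± 1.04, 0.000126), A1bg (-8.23 ± 1.11, 0.000293), Acot3 (-7.40 ± 1.17, 0.0011), Slc22a26 (-7.20 ± 1.03, 0.00052) and Mup10 (-6.92 ± 1.01, 0.000592). The Sult3a1 value hangs on 1 count in all male controls. Without male control 4, Sult3a1 gave -12.87, Cyp2b13 -10.49, Cyp2b9 -10.01, A1bg -9.03, Acot3 -8.95, Cyp4a14 -7.62 and Cyp4a10 -5.05. Sult3a1 and Cyp2b13 gave -9.84 and -8.56 without malnourished male 2, Sult3a1 and Mup10 -13.04 and -8.30 without malnourished female 5, and A1bg -8.85 without malnourished female 1. Slco1a1 differed by -5.81 ± 0.73 (0.000177), Cyp4a14 by -6.15 ± 0.83 (0.000293), Cyp4a10 by -4.07 ± 0.60 (0.000658), Acot4 by -2.64 ± 0.35 (0.000243) and the fatty aldehyde enzyme Aldh3a2 by -1.55 ± 0.26 (0.00201). Prlr gave -2.48 ± 0.31 (0.000177) and Cyp3a44 -3.27 ± 0.35 (7.95e-05). The largest positive differences were the chemokine Cxcl1 (5.72 ± 1.07, 0.00478), Saa1 (4.55 ± 0.80, 0.00311), Saa2 (4.18 ± 0.94, 0.0212), the sphingomyelinase Smpd3 (3.58 ± 0.63, 0.00303), the mucosal peptide Tff3 (3.38 ± 0.68, 0.00858), Cyp7b1 (3.06 ± 0.59, 0.00672), the clock output gene Dbp (3.02 ± 0.69, 0.022) and C6 (2.83 ± 0.55, 0.00701). Male controls ran from 2.12 to 269 CPM of Cxcl1 and from 64.7 to 2250 CPM of Saa1, so these differences rest on the male controls with high acute phase genes. Without controls 1, 2 and 3, Saa2 gave -0.20 and the median of the acute phase list was -0.42 (against 0.55). Without malnourished male 1, Cyp7b1 gave 3.87 and C6 3.50. Without male control 1, Cxcl1 gave 4.18 and Saa1 3.70. Saa2 was not called without male control 1 (3.01, 0.0671) nor Dbp without male control 3 (2.66, 0.0588).

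Coagulation lists had 0 interaction calls over all genes. Medians were -0.07 for procoagulant factors (camera adjusted p = 0.475, 1 member at unadjusted p below 0.05 in edgeR), 0.01 for anticoagulants (0.925), 0.11 for fibrinolysis (0.193, 2 higher over the list alone) and 0.01 for the vitamin K cycle (0.901). F9 gave -0.44 ± 0.14 (0.122), F8 -0.65 ± 0.43 (0.483), Fga 0.37 (0.407) and F11 -0.07 (0.952). In the self-test with 13308 genes, 53.7% of genes changed 2-fold and 14.9% of those changed 1.5-fold were recovered in this comparison, so smaller differences would mostly go unseen.

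Among other lists, male-biased genes had 3 higher, Cyp7b1, C6 and Gstp1 (2.46 ± 0.37, 0.000658), and 1 lower, Slco1a1 (4 and 2 over the list alone). Camera put the list up (adjusted p = 0.0189, lost in 5 of 19 removals of 1 library, highest 0.126, and adjusted p = 0.71 with an estimated correlation), although the median was -0.03 and the mean 0.33. Lipogenesis had 0 higher and 1 lower, Elovl5 (-0.95, 0.0483), with 4 and 1 over the list alone, median 0.61, camera adjusted p = 0.000469, and adjusted p = 0.686 with an estimated correlation. Elovl5 lost its call in 15 of 19 removals of 1 library (highest 0.127, without male control 2). Thrsp gave 1.94 (0.0577) and was called without male control 4, female control 5 or malnourished female 5 (0.011 to 0.0335). Cholesterol synthesis had 1 higher, Dhcr7 (1.01, 0.0328), and 0 lower (2 and 0 over the list alone), median 0.38, camera adjusted p = 1.15e-05, and adjusted p = 0.686 with an estimated correlation. Dhcr7 lost its call in 10 of 19 removals (highest 0.0889, without male control 2). Igf1 gave -0.90 ± 0.23 (0.0502), called without male control 4, malnourished males 2 or 5, female controls 4 or 5 or malnourished female 5 (0.0146 to 0.0466), in a growth hormone list with 0 calls (median -0.27, camera adjusted p = 0.226).

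Acute phase genes had 3 higher, Saa1, Saa2 and Steap4 (2.17 ± 0.47, 0.0169), and 0 lower (6 and 0 over the list alone), median 0.55, camera adjusted p = 0.0819, passing in 5 of 19 removals (lowest 1.37e-05). Complement had C6 higher and Mbl2 lower (-0.86, 0.0048), median 0.18, 0.162. Xenobiotic metabolism had 0 higher and 4 lower (4 and 6 over the list alone), median -0.20, camera adjusted p = 0.0953: Cyp2c37 (-1.78 ± 0.25, 0.000347), Abcc3 (-1.64 ± 0.27, 0.0016), Nr1i3 (-1.61 ± 0.22, 0.000347) and Cyp3a11 (-1.31, 0.0094). Bile acid synthesis had Cyp7b1 higher and Cyp39a1 lower (-0.97, 0.0282; 2 and 1 over the list alone, median -0.04, 0.921), the latter not called without male control 2 or malnourished females 1, 2 or 3 (0.0505 to 0.0627). The amino acid response had 1 lower, the lipoprotein receptor Vldlr (-2.39, 0.00782), median 0.18, 0.587. Markers with 1 call each were Axin2 (-1.80, 0.00964; pericentral, median -0.14, 0.0953), Ctsc (-0.89, 0.0211; periportal, 0.04, 0.285) and Alas2 (1.96, 0.00776; red cell, -0.58, 0.775).

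Kupffer cell (median -0.38) and sinusoidal endothelial markers (-0.55) had 0 calls over all genes, yet both lists moved down by camera. Their adjusted p were 0.00696 and 0.00092, and adjusted p = 0.686 with an estimated correlation for each. The Kupffer call was lost without malnourished male 5 (0.0544) or female control 4 (0.0867). Other lists had 0 calls and did not pass: FXR targets (median -0.33, camera adjusted p = 0.134), urea cycle genes (0.01, 0.587), gluconeogenesis (0.15, 0.308), NRF2 targets (0.22, 0.285), cell cycle (0.08, 0.134), unfolded protein response (-0.06, 0.715, 1 member at unadjusted p below 0.05 in edgeR), oxidative phosphorylation (0.10, 0.0819) and mitochondrially encoded genes (-0.38, 0.251). The same held for markers of stellate cells (-0.04, 0.775), cholangiocytes (0.12, 0.443), T and NK cells (-0.43, 0.285), B cells (-0.60, 0.0819) and neutrophils (2.96, 0.134, 3 higher over the list alone).

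Both responses shared a common part. Among the 13391 genes, 284 rose in both sexes (49.1 expected if the calls were independent) and 268 fell in both (52.1 expected). Nnmt, Cps1, F11, Pros1, Cpb2 and Orm1 fell in both, and Asns, Fgf21, Cd36 and Nqo1 rose in both. Opposite calls were made for 24 genes, 17 higher in males and lower in females (47.5 expected) and 7 the reverse (53.9 expected), and all 24 had an interaction call. A1bg (5.30 in males, 6.10 without male control 4, and -2.94 in females, -3.56 without malnourished female 1), Cyp2c69 (3.94 and -2.13), Cyp3a44 (1.70 and -1.57), Cyp17a1 (1.47 and -1.18) and Gstp1 (-1.57 and 0.89) were among them. In females Cyp17a1 was not called without malnourished females 3, 4 or 5 (0.0502 to 0.0577), nor Gstp1 without female controls 1, 3, 4 or 5 or malnourished females 2, 3 or 4 (0.0543 to 0.0688). Log2 changes of the sexes correlated with Pearson 0.49 and Spearman 0.37. Of genes called in males alone (1421), 187 had an interaction call, and of those called in females alone (783), 51 did.

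The sexes on the control diet (5 females against 4 males) differed in 1267 genes higher and 1157 lower in females, together 18.1%, with 362 and 265 by at least 2-fold. Fewer were lower without male controls 1 (697), 2 (666) or 3 (749) or female controls 1 (757) or 3 (768). Scaling by library size alone moved the median of all genes by 0.133 and the share higher from 52.3% to 76.7%. Among the highest in females were Cyp2b13 (11.34 ± 1.49 (SE), adjusted p = 2.77e-05), A1bg (10.60 ± 0.95, 2.5e-07) and Cyp2b9 (10.47 ± 0.97, 3.05e-07), and Cyp3a41a had a count ratio of 3030 (counting interval 544 to 120000). Among the highest in males were the androgen-driven Cyp4a12a (-11.09 ± 0.99, 2.22e-07) and Mup7 (-8.18 ± 1.09, 3.35e-05), with a Cyp4a12b ratio of 4510 (1250 to 37200). All 25 female-biased genes were higher in females (median 7.09, camera adjusted p = 3.94e-31, and 0.0302 with an estimated correlation). All 23 male-biased genes were lower (median -4.22, camera adjusted p = 1.81e-28, and adjusted p = 0.0631 with an estimated correlation). Of 33 PPARα targets 12 were higher and 1 lower in females (15 and 1 over the list alone), median 0.24, camera adjusted p = 5.56e-06, and adjusted p = 0.491 with an estimated correlation. Cyp4a14 was higher by 5.29 ± 0.68 (2.22e-05), Cyp4a10 by 3.19 ± 0.47 (9.32e-05) and Acot4 by 2.88 ± 0.27 (4.5e-07), and Igfbp1 was lower by 3.20 ± 0.62 (0.0013; 1.83 without male control 1). Without male control 4, Cyp2b13 gave 12.62, A1bg 11.40, Cyp2b9 11.52, Cyp4a14 6.77 and Cyp4a10 4.19, and without female control 2 Cyp4a12a gave -11.71.

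Of 15 procoagulant factors 1 was higher and 3 lower in control females than in control males (median 0.01, camera adjusted p = 0.64). Fga was lower by 0.69, Fgg by 0.58 and Fgb by 0.52, and F7 was higher by 0.38 (0.0343). Without male controls 1 and 2, which held high acute phase genes, no fibrinogen chain was called (-0.46, -0.37 and -0.32, adjusted p 0.146 to 0.25). Fgb was not called without male control 2 (-0.42, 0.0521), nor F7 without male controls 2, 3 or 4 or female controls 1, 3 or 4 (0.0544 to 0.0779). F11 gave -0.54 (0.174). Of 11 anticoagulants 1, the tissue factor pathway inhibitor Tfpi (0.75, 0.0229), was higher and 3 were lower, Serpina10 (-0.49, 0.0278), Hrg (-0.34, 0.0329) and Pros1 (-0.27, 0.0332), with a median of -0.12 (camera adjusted p = 0.742). Tfpi was not called without male controls 1 (0.60, 0.0846) or 2 (0.57, 0.0743), nor Serpina10 (0.0516 to 0.167) without male or female controls 1, 2 or 3. The same was true of Hrg without male controls 1, 2 or 3 or female controls 1, 2 or 4 (0.0514 to 0.124), and of Pros1 without male controls 1, 2 or 3, malnourished male 1 or female controls 1, 2, 4 or 5 (0.0505 to 0.157). Of 7 fibrinolysis genes 1 was lower, Cpb2 (-0.47, 0.0179), not called without male controls 1 (-0.39, 0.083), 2 (-0.42, 0.0664) or 3 (-0.43, 0.0576), with a median of -0.11 (camera adjusted p = 0.635). Kupffer cell markers were higher in females (10 of 10, median 0.73, camera adjusted p = 3.38e-08, and adjusted p = 0.235 with an estimated correlation). Complement was lower (10 of 19 lower and 2 higher, median -0.36, camera adjusted p = 4.91e-05, and adjusted p = 0.351 with an estimated correlation).

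On the malnourishing diet (5 females against 5 males), 975 genes were higher and 1418 lower in females, together 17.9%, with 214 and 215 by at least 2-fold (524 and 888 called without malnourished male 3). Scaling by library size alone moved the median of all genes by 0.143 and the share higher from 40.7% to 76.1%. Sulfotransferases led the genes higher in females, Sult2a3 by 8.25 ± 0.69 (SE, adjusted p = 2.66e-07), Sult2a1 by 7.73 ± 0.89 (1.25e-05), Sult2a5 by 6.16 ± 0.73 (1.83e-05), Sult2a2 by 5.04 ± 0.92 (0.00113), followed by Cyp3a41a by 4.83 ± 0.98 (0.0023; 5.87 without malnourished male 5 and 4.13 without malnourished female 1). Without malnourished male 2 the Sult2a values were 10.81, 8.96, 8.27 and 6.19. Cyp4a12b had a male to female count ratio of 2390 (428 to 94400). Of 25 female-biased genes 17 were higher and 0 lower (18 and 0 over the list alone), median 1.72, camera adjusted p = 1.9e-12, and adjusted p = 0.24 with an estimated correlation. Of 23 male-biased genes 22 were lower and 0 higher, median -3.33, camera adjusted p = 1.05e-16, and adjusted p = 0.262 with an estimated correlation. Of 33 PPARα targets 10 were lower and 0 higher (11 and 1 over the list alone), median -0.38, camera adjusted p = 2.89e-05, and adjusted p = 0.413 with an estimated correlation. Cyp4a14 gave -0.86 ± 0.51 (0.266), Acot4 0.25 (0.494) and Cyp4a10 -0.87 (0.135), the last called without male control 4 (-0.87, 0.0276). Igf1 was lower in females by 0.74 ± 0.16 (0.00388) and the gluconeogenic Pck1 by 2.23 ± 0.41 (0.00108).

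In lipogenesis 11 of 18 were higher and 1 lower in malnourished females than males, median 0.87, camera adjusted p = 1.79e-05, and adjusted p = 0.38 with an estimated correlation. In cholesterol synthesis 13 of 24 were higher and 0 lower (17 over the list alone), median 0.68, camera adjusted p = 4.31e-10, and adjusted p = 0.38 with an estimated correlation. Fasn, fatty acid synthase, was higher by 1.84 (0.00272) and the regulator Srebf1 by 1.55 (0.00119). Among procoagulant factors 1 was higher, F7 (0.40), and 3 lower, F9 (-0.64), Klkb1 (-0.50, 0.0224) and Fgg (-0.47), median -0.14, camera adjusted p = 0.154. F7 was not called without malnourished male 3 (0.33, 0.07) or female 1 (0.34, 0.0634), nor Fgg without male 3 or females 2 or 4 (0.0517 to 0.0634), nor Klkb1 without males 1 or 3 or female 4 (0.0559 to 0.0813). Fga gave -0.32 (0.135), Fgb -0.26 (0.141) and F11 -0.61 ± 0.26 (0.107), which was called without malnourished female 5 (-0.87, 0.0189). Of 11 anticoagulants 2 were lower, Pros1 (-0.34, 0.00727) and Hrg (-0.36, 0.0183; -0.28 and 0.0587 without malnourished male 1), median 0.03, 0.723. Of 7 fibrinolysis genes 1 was higher and 1 lower, the latter Cpb2 (-0.48, 0.0128), median 0.38, 0.465. Cyp7a1 was higher by 2.30 ± 0.66 (0.0208), not called without malnourished male 3 (2.08, 0.0612) or female 4 (1.99, 0.058).

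Sex-biased genes were also chosen from part of the controls and their diet response measured against the others. The 634 genes biased to females had a median diet response of 0.322 in males and -0.022 in females, with 76.7% and 47% positive. The 446 genes biased to males had medians of -0.58 and -0.172, with 9.42% and 32.5% positive. In 20 simulated sets without a diet effect, the male medians ran from -0.028 to 0.021 and from -0.045 to 0.026. Between control sexes the sets gave 0.956 to 1.181 (female-biased, 0.531 in the data), so they do not measure chance. With the parts exchanged (194 and 202 genes), the medians were 0.929 and 0.101 for female-biased and -1.07 and -0.384 for male-biased genes.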

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

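No test in this part was chosen after its result was seen, but the genes it was applied to include some named after their values had been seen. A Dixon test of extremes was run on 210 quantities in each of the 4 groups of libraries. It marked 60 single values in these 840 tests, and about 5 in 100 tests would give a mark by chance. Values are CPM unless a list score (log2) is named.

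In male controls, replicate 1 was highest for Igfbp1 (788), Nr0b2 (60.3) and Orm3 (13.7), replicate 2 for Cyp3a41a (0.0389), and replicate 3 lowest for Hba-a2 (10.6). Replicate 4 was highest for Cyp2b9 (1.04), Cyp4a14 (53.7), Sult2a1 (0.741), Sult2a3 (0.0674) and Sult3a1 (0.0337), and lowest for Cd79b (0.572), Igfbp2 (377) and the complement score (0.51).

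In malnourished males, replicate 1 was highest for Cyp7b1 (77.9), Mup7 (725), Moxd1 (0.0392), Proz (509), Serpina10 (253) and Susd4 (4.74). Replicate 2 was highest for Sorcs2 (2.19), Sult2a3 (0.523), Sult2a5 (1.83) and Sult3a1 (0.752), and lowest for Hba-a1 (74.9) and Nr1h4 (96.9). Replicate 3 was highest for Cd79a (1.76). Replicate 4 was highest for Alas1 (236), Gstm3 (96.9) and Phgdh (8.21) and lowest for the gluconeogenesis score (-0.41). Replicate 5 was lowest for mt-Co1 (5590) and the mitochondrially encoded score (-1.04).

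In female controls, replicate 1 was highest for Abcb11 (984), Abcb4 (314), Cdc20 (6.42) and Pdk4 (17). Replicate 4 was highest for Orm3 (9.36), Sult2a3 (2.14), Timd4 (19) and the Kupffer cell score (0.99), and lowest for Gm3839 (0.713), Igfbp1 (16.6), Nr1i3 (49.8) and the mitochondrially encoded score (-0.54). Replicate 5 was highest for Cyp7a1 (204) and Srebf1 (1090).

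In malnourished females, replicate 1 was highest for A1bg (49.1), Mbl2 (732) and Orm1 (140), and lowest for Osgin1 (313). Replicate 2 was highest for Cyp4a12b (0.034) and lowest for Cyp8b1 (135) and S100a8 (0.34), and replicate 3 was highest for Smpd3 (7.09). Replicate 5 was highest for C8a (215), Moxd1 (0.0282), Mup10 (7.86), Mup13 (1.72), Ppara (91.3) and Sult3a1 (0.479).

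The diet response differed between the sexes for 280 genes. Lists that differed, with camera adjusted p, were female-biased (2.84e-26) and male-biased genes (0.0189), PPARα targets (1.58e-20), cholesterol synthesis (1.15e-05), lipogenesis (0.000469), endothelial (0.00092) and Kupffer markers (0.00696). With an estimated correlation 0 lists passed (lowest 0.0607), and the male-biased list had a median of -0.03 and lost its call in 5 of 19 removals of 1 library. Named genes with a positive log2 difference (female minus male response, which can mean a smaller fall in females) were Cxcl1 (5.72), Saa1 (4.55), Saa2 (4.18), Smpd3 (3.58), Tff3 (3.38), Cyp7b1 (3.06), Dbp (3.02), C6 (2.83), Gstp1 (2.46), Steap4 (2.17), Alas2 (1.96) and Dhcr7 (1.01). Those with a negative one were Sult3a1 (-11.18), Cyp2b13 (-9.21), Cyp2b9 (-8.97), A1bg (-8.23), Acot3 (-7.40), Slc22a26 (-7.20), Mup10 (-6.92), Cyp4a14 (-6.15), Slco1a1 (-5.81), Cyp4a10 (-4.07), Cyp3a44 (-3.27), Acot4 (-2.64), Prlr (-2.48), Vldlr (-2.39), Axin2 (-1.80), Cyp2c37 (-1.78), Abcc3 (-1.64), Nr1i3 (-1.61), Aldh3a2 (-1.55), Cyp3a11 (-1.31), Cyp39a1 (-0.97), Elovl5 (-0.95), Ctsc (-0.89) and Mbl2 (-0.86).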

How the results depend on the processing

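The removals of male controls 1 and 2, and of 1, 2 and 3, were chosen after values had been seen, and all other alternatives before the data were examined. Under some alternative the call changed for 160 of 308 gene results and 56 of 78 list results, and for every change below the cause was not tested unless stated.

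Asking for 2-fold changes, fewer genes pass by construction: 383 and 325 in males (higher and lower), 242 and 200 in females, 76 and 119 in the interaction, 362 and 265 between control sexes and 214 and 215 between malnourished sexes. Library size alone gave 1161 and 425 in females, 557 lower between control sexes, 2040 and 639 between malnourished sexes, and 466 higher in both sexes. Voom with quality weights gave 1367 and 1448 in females, 305 and 350 in the interaction, 1939 lower between control sexes and 421 lower in both sexes. DESeq2 called 245 and 366 in the interaction. With 2 groups only, males had 627 and 617 and control sexes 724 lower.

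Replicate numbers do not pair mice (correlations of -0.113 to 0.114). With them as a block, 901 and 1055 genes were called in males and 636 and 600 in females, procoagulant factors passed in males (0.044) and anticoagulants did not (0.056).

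Without the 62 series libraries, the interaction had 380 and 470 genes. Male procoagulant factors passed (0.0282), and female PPARα targets (0.0618) and male-biased genes in the interaction (0.0894) did not.

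Without male controls 1 and 2, genes called were 402 and 451 in males, 43 and 65 in the interaction, 449 and 382 between control sexes and 176 higher in both sexes. Without 1, 2 and 3, leaving 1 control, they were 66 and 106, 4 and 4, 65 and 120, and 31 higher and 54 lower in both sexes. Signs then turned for S100a8 (0.984), S100a9 (1.05), Plaur (0.052) and Retnlg (5; 0.055 without 1 and 2) in males, Saa2 in the interaction (-0.20) and Serpina10 between control sexes (0.19). Lists that turned were the unfolded protein response (0.00358) and endothelium (0.031; 0.474 without 1 and 2) in males, and acute phase (0.000325) and endothelium (0.307) in the interaction. Male anticoagulants (0.366) and fibrinolysis (0.383; 0.0956 without 1 and 2) were lost, and procoagulant factors passed in the interaction (0.023).

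Leaving out 1 library gave 433 (female control 3) to 712 (malnourished male 5) genes lower in females. The interaction ran from 63 (male control 2) to 240 (female control 5) higher and 95 (male control 2) to 379 (male control 4) lower. Genes lower between control sexes ran from 666 (male control 2) to 1378 (female control 5). Between malnourished sexes they ran from 524 to 1113 higher (malnourished males 3 and 4) and 888 to 1605 lower (malnourished males 3 and 5). List values ran from 0.0215 to 0.162 for male procoagulant factors, 0.0215 to 0.0838 for male anticoagulants, 0.000802 to 0.105 for female PPARα targets and 2.18e-05 to 0.126 for male-biased genes in the interaction.

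With an estimated correlation no diet list passed. In males the adjusted p were 0.137 for PPARα targets, male-biased and female-biased genes, 0.195 for FXR targets and fibrinolysis and 0.262 for anticoagulants. In females they were 0.171 for anticoagulants, 0.188 for procoagulant factors, 0.228 for female-biased and 0.329 for male-biased genes and 0.66 for PPARα targets, and in the interaction 0.0607 for female-biased genes, 0.212 for PPARα targets and 0.71 for male-biased genes. The test fry gave 0.0308 (mixed 0.00631) for male procoagulant factors, mixed 0.0978 for male fibrinolysis, 0.307 for female PPARα targets, mixed 0.00163 for female FXR targets and 0.48 for male-biased genes in the interaction. With members of at least 2 CPM, female fibrinolysis passed (0.0435) and the male-biased interaction did not (0.0634). With the control parts exchanged, female-biased genes gave 0.101 for the female response (against -0.022) and 1.376 between control sexes (against 0.531).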

Other observations

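All tests in this part were chosen after the pattern was seen, except the clock test and the splits, whose predictions were written before their results.

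Of 25 female-biased genes 19 rose in malnourished males, unevenly between mice, and the 25 closed 0.1% to 58.7% of the gap to control females (list adjusted p = 0.137 with an estimated correlation). The list median was 2.67 in males and -0.55 in females, but 634 female-biased genes chosen from separate controls gave -0.022 in females, so a general loss there was not shown. Female RNA carried into the male libraries would have lowered 4 Y-linked genes by 0.25, but they gave 0.05 (SE 0.08), which argues against it. The acute-phase state of male controls 1, 2 and 3 is argued against as the whole cause. Without controls 1 and 2 the acute phase median went from -1.02 to -0.34, while the female-biased median was 2.69 (SE 0.52 from the spread within the 4 groups) with 17 called (2.59 and 3 against control 4 alone). An altered growth hormone pattern could lie behind it, but the test leaves this open because Cux2 rose (3.76) while Bcl6 gave 0.69 (SE 0.41) and was not called.

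Most PPARα targets rose in males, and 12 of 33 were already higher in control females (list adjusted p = 0.491 with an estimated correlation). The called sex difference of Cyp4a14 on the control diet (5.29) was not called on the poor diet (-0.86). Without male controls 1 and 2 the male median was 0.62 (SE 0.24) against 0.72 with all 4 and the interaction median -0.44 against -0.68 (0.68 and -0.51 against control 4 alone), while members called went from 26 and 11 to 18 and 7. With so wide a spread, the acute-phase controls stay open as part of the source. Clock genes, looked at after values were seen, also moved in males (Npas2 2.85, Arntl 1.22, Dbp -3.00, 3 higher and 8 lower of 18), and the time of collection was not given. With a clock score as covariate the male median was 0.66 (SE 0.29) and the interaction median -0.52, with 11 and 3 members called. Over all genes 136 and 125 were then called in males and 8 and 31 in the interaction, while the female-biased median stayed at 2.69. The scores of the male groups do not overlap (lowest malnourished 2.08, highest control 0.79), so calls are lost either way, and for PPARα targets clock phase and diet cannot be told apart.

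Male controls 1, 2 and 3 carried high acute phase genes (Saa1 2250, 1120 and 489 CPM against 64.7 in control 4), and this matters for several male and interaction results. Control 4 is also the only male control of the 62 label series. In malnourished males and female controls the 62 series library differed from group mates by -0.1 (SE 0.2) in acute phase score. That argues against a series shift in all groups (-1.76 in male controls). Saa1 was low in those groups, so a series effect in male controls alone, or inflammation in male controls 1 to 3, stays open. The neutrophil marker S100a8 had the same order (6.72, 2.69 and 1.51 CPM against 0.303), but only RNA was available. Part of the fall on the poor diet was shared by the sexes, since Orm1 fell by 2.88 and 2.92.

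For gene counts, few of 75 splits (1 of them real) reached the real grouping, but splits of single mice with unknown litters cannot exclude chance. As many genes were called in 1 of 75 splits for males (1997 against at most 1875 in another), 1 for females (1359 against 4), 1 for control sexes (2424 against 1847), 1 for malnourished sexes (2393 against 75) and 1 for genes shared by both sexes (552 against 0). For the interaction it was 3 of 75 (280, with 1240 in another split). Splits also broke the diet effects, so they do not measure chance for the interaction or for shared genes. Chance could not be excluded for list counts, reached in 5 splits for males (19 lists against 20), 6 for females (18 against 19) and 61 for the interaction (7 against 21).

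For coagulation, a sex difference of the diet response was not shown at RNA level. F11 fell 2.04-fold in males and 2.14-fold in females, and F9 was called in females. Serpina10 was called in males, resting on the higher controls (215 to 437 CPM, against 169 to 253 on the poor diet). No clotting gene had an interaction call. A follow-up is plasma activity of factors IX and XI in both sexes, with collection time recorded.

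Some single genes, chosen after values were seen, invite a closer look. Nnmt nearly vanished in both sexes (-6.6 and -6.41). Lepr, the leptin receptor, rose in males (4.43, adjusted p = 1.63e-06), from 3.06 ± 1.1 to 66.8 ± 43.9 CPM, and in females (1.15, 0.0337), from 30.1 ± 10.4 to 66.9 ± 15.4 CPM.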
